A study of Mus musculus with 4 samples.

How the data were processed

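Gene expression was measured on 4 Affymetrix whole-transcript arrays, each hybridised with biotinylated cRNA made from total RNA of mouse invariant natural killer T (iNKT) cells. Per the labels' protocols, RNA was taken from frozen tissue with an RNeasy Plus column kit and labelled by the array maker's method. The sample source is given as iNKT cells, and the mention of tissue leaves it uncertain whether the RNA came from sorted cells alone. Groups were read from the genotype label of each sample: 2 arrays carried RNA of iNKT cells of CD4-Vα14Tg mice and 2 carried RNA of iNKT cells of wild-type (WT) mice. The labels give neither the organ the cells came from nor their sorting gate, age or sex.

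The deposited values are on the log2 scale, 1 value per probe set and array, and per the submitters' processing notes they were made with RMA (background correction, quantile normalization over arrays and summary of probes) and Affymetrix Power Tools. The versions, the options and the genome build are not given in the sources used here. The log2 scale was read from the values themselves: 41345 probe sets with array medians from 5.04 to 5.07, no missing values and maxima from 13.7 to 13.8. Quantile normalization gives arrays nearly the same distribution of values, so a shift of total RNA per cell cannot be seen in these data. Probe sets near background compress differences, and fold changes of genes near background are therefore understated.

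Probe sets were named from the platform annotation table: 23521 had 1 gene symbol, 1814 had several and 16010 had none there. Only probe sets with 1 symbol were used for named genes, and they covered 22180 genes, of which 21994 were found by Entrez number in a RefSeq gene table of assembly GRCm38.p6, used for names alone. No coordinates are given, since the build behind the array annotation is not stated. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was kept. A gene was tested when it lay at or above the 40th percentile of the named probe sets on at least 2 of the 4 arrays, which left 13602 genes and set 8578 aside as dim.

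Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, CD4-Vα14Tg minus WT, two-sided), and p-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Every adjusted p of a gene is from this model, and each ± is the SD of 2 arrays on the log2 scale. Fold changes are 2 raised to the absolute difference of group means. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

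Gene lists were written from general knowledge of iNKT subsets, thymic development, T cell receptor signalling and other cell types, and 500 of their 567 entries matched a named gene. One key gene is not reported here. Of 27 lists, the 24 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. They were tested again with camera at an estimated correlation, with fry, which asks whether the genes of a list move one way on balance, and against 10000 random lists of the same size matched on mean expression. Some genes stand in several lists. Slamf7 and Cxcr3 of the NKT1 list are also SLAM and homing genes. Ccr7 and Lef1 are in both the precursor and the naive T cell list, Lef1 also in the NKT2 list and Ccr7 also in the homing list. Ccr9 is in the precursor, homing and dendritic cell lists. Rises in these lists are therefore not independent of each other.

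The rule for named genes took the 10 largest rises and 10 largest falls among genes past the threshold whose groups of arrays did not overlap, a list of key iNKT genes whatever their test, and up to 4 members of each list described, by absolute moderated t. Gene models without an established symbol, olfactory and vomeronasal receptors and small RNAs were skipped in the first part: 11 of the genes called higher and 6 of those called lower. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Which 14 lists had members named was settled afterwards, when it was already known which genes changed sign under the alternatives. The lists left without members were mostly markers of other cell types, so the genes followed through the alternatives are fewer than if all lists had been described. Also chosen after seeing the values were the gene families, the small RNA comparison, the fit without small RNA genes and the counts of list members under each alternative.

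The pipeline was tested on simulated data made from the 13602 genes of CD4-Vα14Tg against WT with 2 arrays each. Noise was drawn independently for each gene, with spreads from limma's own fitted distribution, so the simulated data obey the model by design. Correlated genes and other differences between samples were not simulated, so the error rates may not hold for the real arrays. With 200 genes changed 2-fold, 80.5% were recovered, with 5 false calls among 166. With 200 genes changed 4-fold, 99.5% were recovered, with 16 false calls among 215, and with no gene changed there were 0 calls. Alternatives covered the dim filter, a second normalization, the variance model, array weights, the mean of a gene's probe sets, the replicate number as a block and leaving out each array. The number of arrays, 2 per group with 2 residual degrees of freedom, limits the precision of every value. The labels do not say that replicates came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.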

Results

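The expression profile of iNKT cells was compared between CD4-Vα14Tg mice, which carry a Vα14 T cell receptor (TCR) α chain transgene under the CD4 promoter, and WT mice. iNKT cells are T cells with a semi-invariant TCR that recognise lipids presented by CD1d, and they mature into interferon-γ-producing NKT1, interleukin-4-producing NKT2 and interleukin-17-producing NKT17 subsets. The comparison asked how the transcriptome of iNKT cells differs when the TCR α chain comes from the transgene. Each genotype was measured on 2 arrays. Correlations across probe sets of named genes, which are not independent replicates, were 0.989 between the CD4-Vα14Tg arrays, 0.990 between the WT arrays and 0.977 to 0.983 between arrays of different genotype. The median SD between arrays was 0.10 in CD4-Vα14Tg and 0.098 in WT on the log2 scale.

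CD4-Vα14Tg iNKT cells had lower expression of 182 genes, among them 28 of 42 tested NKT1 and NKT17 program genes, and higher expression of 83 genes, among them Irak3, Syne1, Itga4, Themis, S1pr1 and Ccr7. Among genes kept by the naming rule, the largest measured falls were in Klra5, an Ly49 family receptor, at 25.2-fold (5.83 ± 0.12 against 10.5 ± 0.22, n = 2 arrays each, limma adjusted p = 8.42e-05), and Il23r, the interleukin-23 receptor, at 20.9-fold (3.53 ± 0.29 against 7.92 ± 0.47, limma adjusted p = 4.22e-04). Il1r1, the type 1 interleukin-1 receptor, was 12.7-fold lower, the granzymes Gzma and Gzmb were 9.47-fold and 7.08-fold lower, and the NK receptors Klre1, Klra9, Klrc2 and Klrc1 were 7.95-fold, 5.66-fold, 5.10-fold and 4.94-fold lower. The Src family kinase gene Blk was 5.07-fold lower. Il23r, Il1r1 and Klrc2 lay below the 40th percentile of their arrays in CD4-Vα14Tg cells, so their folds are set against background.

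Among genes kept by the naming rule, the largest measured rise was in Irak3, a negative regulator of Toll-like receptor signalling, at 6.09-fold (8.35 ± 0.12 against 5.75 ± 0.10, n = 2 arrays each, limma adjusted p = 4.09e-04). Probe sets without a gene symbol of their own, given below, rose by up to 5.89 on the log2 scale. Moxd1, a monooxygenase-like gene that lay below the 40th percentile in WT cells, was 5.66-fold higher, and Syne1, which encodes the nuclear envelope protein nesprin-1, was 5.26-fold higher. All 59 probe sets of Syne1 were higher, by 0.71 to 3.04 on the log2 scale. Igfbp4, an insulin-like growth factor binding protein, rose 3.92-fold, the integrin α4 gene Itga4 rose 3.76-fold and Themis, a thymocyte selection protein of the TCR signalling pathway, rose 3.18-fold. S1pr1, the receptor for tissue egress along sphingosine-1-phosphate, rose 2.98-fold, the focal adhesion gene Tns4 rose 2.94-fold, and the chemokine receptor genes Ccr7 and Ccr9 rose 2.94-fold and 2.83-fold.

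Of 13602 genes tested, 265 passed limma's test, 83 higher and 182 lower in CD4-Vα14Tg cells, so that 68.7% of the calls were lower. At least 2-fold differences were found for 36 of the higher and 100 of the lower genes. The size of the called differences ran from 0.64 to 4.66 on the log2 scale with a median of 1.01, while the median difference of all genes was -0.022. At least a 1.5-fold difference with an unadjusted p under 0.01 was seen for 468 genes, 157 higher and 311 lower, and 731 genes had such a p at any fold where 136 are expected by chance. The arrays of the groups did not overlap for 39.1% of genes, against 33.3% by chance. The count of calls was 169 without CD4-Vα14Tg replicate 1, 166 without CD4-Vα14Tg replicate 2 and 166 without WT replicate 2.

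**Figure D1:**
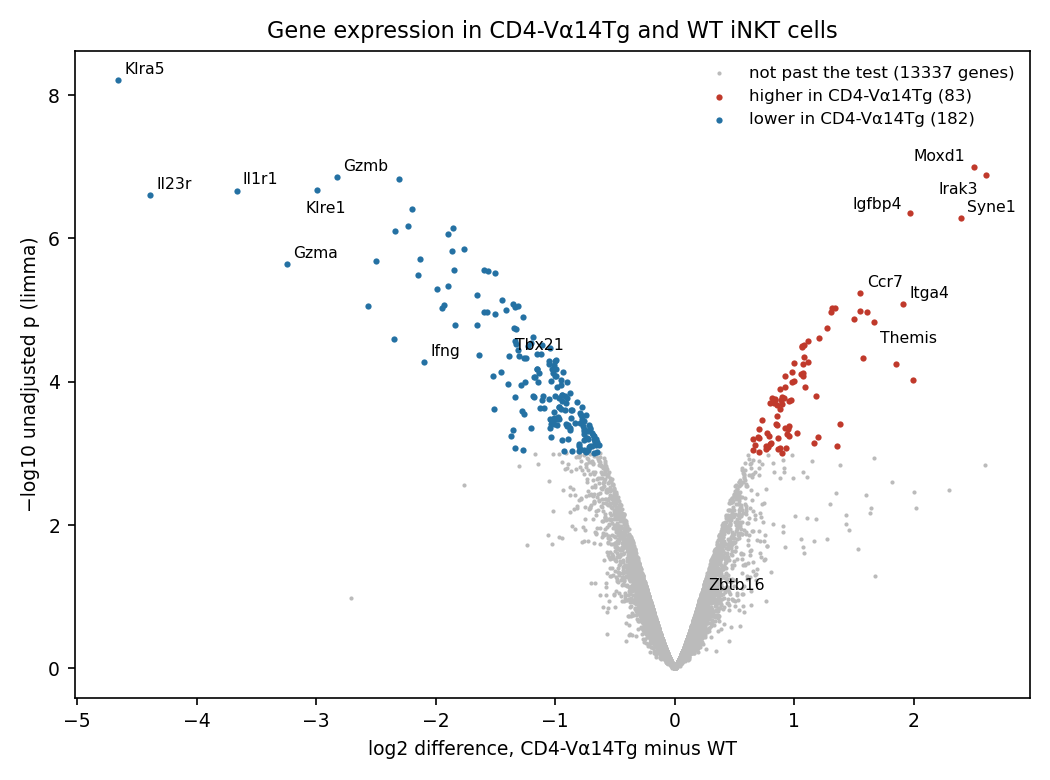
Each point is 1 of the 13602 genes tested, with the log2 difference between CD4-Vα14Tg and WT iNKT cells (2 arrays each) on the x axis and −log10 of the unadjusted limma p on the y axis. The 182 genes called lower (blue) reach a difference of -4.66 for Klra5. Of the 83 called higher (red), Irak3 is at 2.61, the largest among genes kept by the naming rule.

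Genes of the NKT1 program were lower in CD4-Vα14Tg cells: 21 of 26 tested members fell, 0 rose and 5 did not pass, with a median log2 difference of -1.36, or 2.57-fold. Besides the granzymes, these included Tbx21, the gene of the NKT1 master regulator T-bet, at 2.62-fold (7.60 ± 0.27 against 8.99 ± 0.11, limma adjusted p = 0.00819), Ifng, the gene of interferon-γ, at 4.27-fold (limma adjusted p = 0.00889), Klrb1c, which encodes NK1.1, at 2.72-fold (limma adjusted p = 0.00326) and Klrd1, the CD94 partner of NKG2 receptors, at 4.69-fold (limma adjusted p = 7.44e-04). Il2rb, the interleukin-2 and interleukin-15 receptor β chain, fell 1.74-fold (limma adjusted p = 0.0427), a call lost without any 1 array (0.0590 to 0.179), with no filter (0.0576) and with quantile normalization (0.0730). With p-values adjusted over the list alone, 24 members were lower. The camera test gave an adjusted p of 5.51e-39 for the list, and the adjusted p was 0.298 with an estimated correlation.

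Genes of the NKT17 program were also lower, with 7 of 16 tested members falling, 0 rising and 9 not passing, and a median log2 difference of -0.76. Il23r, Il1r1 and Blk led the list, and Serpinb1a, a serine protease inhibitor, fell 1.94-fold (limma adjusted p = 0.0131, a call lost without replicate 2 of either group). Il17a itself was 4.58 ± 0.52 against 5.55 ± 0.54, a log2 difference of -0.97 that did not pass (limma adjusted p = 0.228) and ranged from -1.34 to -0.59 when 1 array was left out. With p-values adjusted over the list alone, 11 members were lower and 1 was higher. The camera adjusted p was 2.95e-11, and the adjusted p was 0.298 with an estimated correlation. The number of NKT17 genes lower was 4 without CD4-Vα14Tg replicate 1, 4 without CD4-Vα14Tg replicate 2 and 3 without WT replicate 2.

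The NKT2 program did not pass the set test: 2 of 15 tested members rose, 0 fell, the median log2 difference was -0.03 while the mean was 0.10, and the camera adjusted p was 0.169. The 2 that rose were Lef1, a transcription factor downstream of Wnt signalling, at 1.79-fold (limma adjusted p = 0.0173), and Il6ra, the interleukin-6 receptor, at 1.74-fold (limma adjusted p = 0.0184). Neither call was steady: Il6ra lost it without any 1 array (adjusted p from 0.0709 to 0.0782) and Lef1 without 3 of the 4 (0.0633 to 0.0733). The cytokine genes Il4 and Il13 had log2 differences of -0.56 (-0.81 to -0.31 when 1 array was left out) and -0.57 (limma adjusted p = 0.234 and 0.0625), and the chemokine receptor gene Ccr4 had 0.60 (limma adjusted p = 0.0937). Adjusted over the list alone, 3 members were higher and 2 lower. Zbtb16, the gene of PLZF, the transcription factor that defines the iNKT lineage, was 11.3 ± 0.09 against 11.1 ± 0.03, a log2 difference of 0.23 with a 95% interval from -0.05 to 0.51 (limma adjusted p = 0.567). Gata3, a regulator of NKT2 cells, differed by -0.03 with an interval from -0.36 to 0.30 (limma adjusted p = 0.983).

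**Figure D2:**
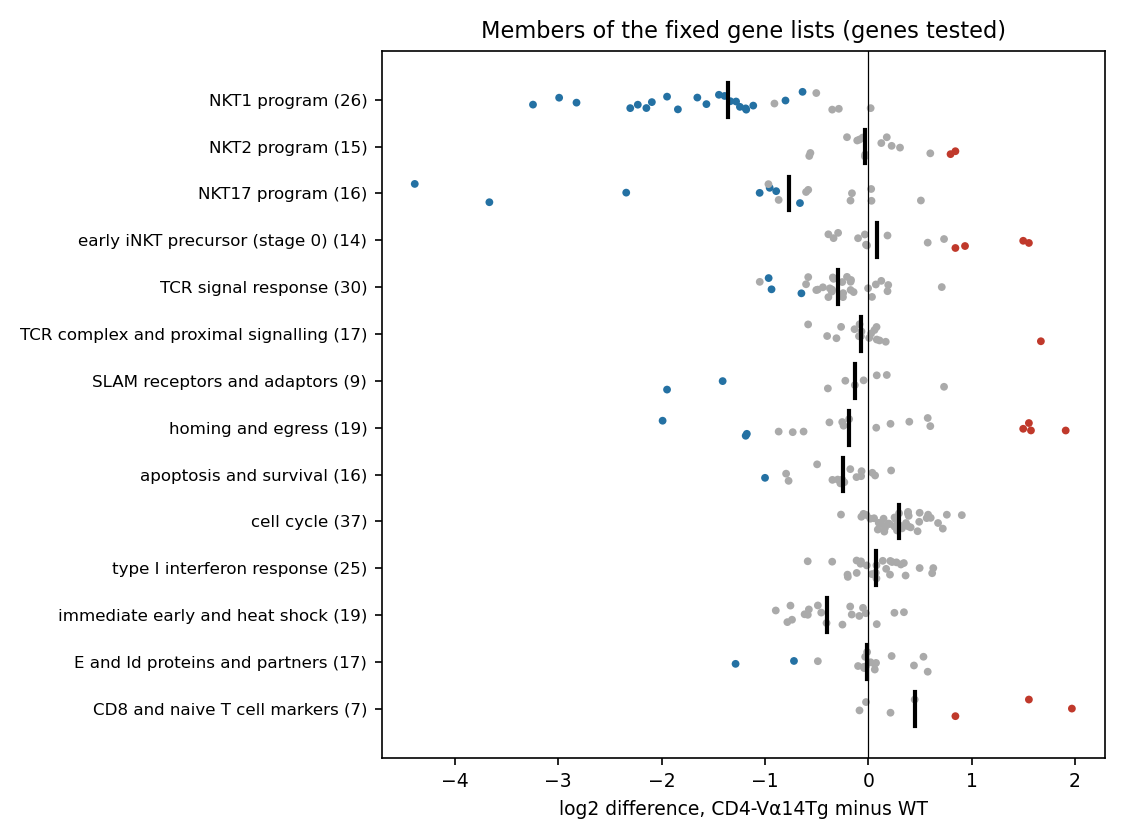
Each point is a tested gene of the list named on the y axis, placed by its log2 difference between CD4-Vα14Tg and WT iNKT cells, with the number of genes tested in brackets. Blue and red points are genes called lower and higher, grey points did not pass, and black bars are list medians, which reach -1.36 for the NKT1 program and 0.45 for the CD8 and naive T cell markers.

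Some early precursor, naive T cell and trafficking genes were higher in CD4-Vα14Tg cells. Of 14 early iNKT precursor genes, Ccr7, Ccr9, Lef1 and Sox4, a transcription factor of early thymocytes (1.91-fold, limma adjusted p = 0.0347, a call lost without 3 of the 4 arrays), rose, 0 fell and 10 did not pass, with a median log2 difference of 0.09 and a mean of 0.37. The difference was positive in 7 of the 14 and negative in 7. Ccr7 was 9.34 ± 0.14 against 7.79 ± 0.10 (limma adjusted p = 0.00281). The precursor list had a camera adjusted p of 4.26e-04, which became an adjusted p of 0.488 with an estimated correlation, and 6 members were higher when adjusted over the list alone. Its count of rises was 2 without CD4-Vα14Tg replicate 1 and 2 without WT replicate 1, and its median was 0.19 without WT replicate 2 and 0.06 without WT replicate 1. Cd24a, a marker of the earliest precursors, lay below the filter at 4.47 ± 0.05 against 4.51 ± 0.09, and Cd44, which rises as iNKT cells mature, was 7.91 ± 0.09 against 8.64 ± 0.20 (log2 difference -0.73, limma adjusted p = 0.0550).

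Beside these, 3 of 7 CD8 and naive T cell markers rose (Igfbp4, Ccr7 and Lef1) and 0 fell, with a median log2 difference of 0.45, while Actn1, an actin cross-linker, had 0.45 (limma adjusted p = 0.154). The CD8 genes themselves showed no rise, though both were dim. Cd8b1 had a log2 difference of -0.085 and read from 5.24 to 5.52 on the arrays. Cd8a lay below the filter and is not among the 7, with a log2 difference of 0.034 and values from 4.38 to 4.60. The camera adjusted p of that list was 4.34e-06 and its adjusted p was 0.488 with an estimated correlation. Adjusted over the list alone, 4 markers were higher. Homing and egress genes went both ways, with 4 of 19 higher (Itga4, S1pr1, Ccr7 and Ccr9) and 3 lower. Those lower were Itga1, the collagen-binding integrin α1, at 3.97-fold (limma adjusted p = 0.00255), Cxcr3, the receptor for interferon-induced chemokines, at 2.28-fold, and Itgae, the integrin αE chain CD103, at 2.26-fold. The median of the homing list was -0.19 while its mean was 0.04 and camera's direction was up (adjusted p = 0.922). Adjusted over the list alone, 5 were higher and 6 lower.

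Genes that respond to TCR signals were mostly lower, with a negative difference in 24 of 30, though few passed singly. Of the 30, 3 fell, 0 rose and 27 did not pass, with a median log2 difference of -0.29. The 3 were Egr1, an immediate early transcription factor (9.21 ± 0.14 against 10.2 ± 0.14, 1.95-fold, limma adjusted p = 0.0171), Dusp2, a MAP kinase phosphatase, at 1.91-fold (limma adjusted p = 0.0107), and Tnfrsf18, which encodes GITR, at 1.57-fold (limma adjusted p = 0.04996, just under the threshold, a call lost without any 1 array). Egr2, Nr4a1, Cd69 and Cd5, all used as readouts of TCR signal strength, had log2 differences of 0.19, -0.34, -0.39 and -0.002 (limma adjusted p = 0.699, 0.584, 0.361 and 0.999), and Nfkbid had -0.58 (limma adjusted p = 0.0678). When 1 array was left out, Egr2 ranged from 0.07 to 0.30, Nr4a1 from -0.59 to -0.08, Cd69 from -0.57 to -0.21 and Cd5 from -0.18 to 0.18. The camera adjusted p was 1.25e-05, and the adjusted p was 0.298 with an estimated correlation. Adjusted over the list alone, 6 were lower, and without WT replicate 2 the count of falls was 1. Egr1 had a limma adjusted p of 0.0733 without CD4-Vα14Tg replicate 1 and 0.0778 without WT replicate 2.

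Immediate early and heat shock genes, which also respond to handling of cells, shifted the same way, with a median log2 difference of -0.40 over 19 genes, of which 0 passed limma's test and 9 had an unadjusted p under 0.05. Ier2, Ier3, Jund and Atf3 had log2 differences of -0.90, -0.75, -0.62 and -0.74, with limma adjusted p from 0.0503 to 0.0847. Ier2 passed without CD4-Vα14Tg replicate 1 (limma adjusted p = 0.0215) and Atf3 without WT replicate 1 (limma adjusted p = 0.03455). The camera adjusted p was 8.28e-05, it was 0.0773 without WT replicate 2, and the adjusted p was 0.488 with an estimated correlation. Adjusted over the list alone, 8 were lower. Genes of the TCR complex and proximal signalling showed 1 rise, Themis (limma adjusted p = 0.00408), and 0 falls among 17, with a median of -0.07 and a mean of 0.01 (camera adjusted p = 0.922), and adjusted over the list alone 1 was higher. Ptpn22, Ptpn6 and Cd3e had log2 differences of -0.58, -0.40 and -0.31, none past the test, and the co-receptor gene Cd4 had -0.08. The TCR α genes Trac, Trav11 and Traj18 were not analysed here, having no probe set named with them alone.

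**Figure D3:**
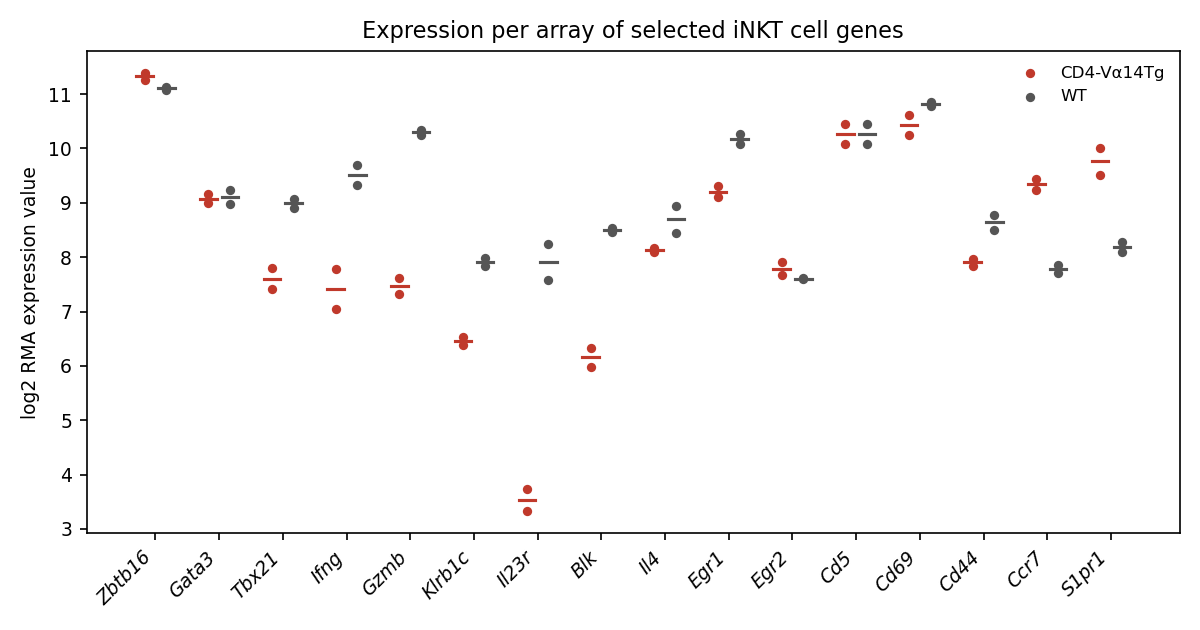
Log2 RMA expression values (y axis) of 16 iNKT cell genes (x axis), with 1 point per array and a bar at the mean of the 2 arrays of each genotype. Tbx21, Ifng, Gzmb, Klrb1c, Il23r, Blk and Egr1 passed the test as lower in CD4-Vα14Tg cells and Ccr7 and S1pr1 as higher, while Cd5 had 10.3 in both.

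Among SLAM family receptors and adaptors, which take part in iNKT selection, 2 of 9 fell and 0 rose. Slamf7 fell 3.85-fold and Cd244a, the NK receptor 2B4, fell 2.66-fold (limma adjusted p = 0.00326 for both), while Slamf6 and Cd48 had log2 differences of 0.73 and -0.39 (limma adjusted p = 0.0603 and 0.249). The list median was -0.13 (camera adjusted p = 0.107, and 0.0463 without WT replicate 1), and adjusted over the list alone 1 was higher and 3 lower. Of 17 E and Id protein genes and partners, Runx3, a transcription factor of cytotoxic lineages, fell 2.44-fold (limma adjusted p = 0.0130) and Mxd4, a MYC antagonist, fell 1.65-fold (limma adjusted p = 0.0450, a call lost without any 1 array). Id3 and Runx1 had log2 differences of 0.58 and 0.53 (limma adjusted p = 0.0848 and 0.0849). That list had a median of -0.01 against an upward camera direction (adjusted p = 0.753), with 3 higher and 3 lower when adjusted over the list alone. Of 16 apoptosis and survival genes, Bcl2a1a, an anti-apoptotic BCL2 relative with near-identical copies, fell 2.00-fold (limma adjusted p = 0.00873), and Bcl2l11, Bcl2 and Traf1 had log2 differences of -0.80, -0.77 and -0.50, none past the test. The apoptosis list had a median of -0.24 (-0.15 without CD4-Vα14Tg replicate 2), a camera adjusted p of 9.59e-04, an adjusted p of 0.488 with an estimated correlation, and 2 members lower when adjusted over the list alone.

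Cell cycle genes were slightly higher as a group: 33 of 37 had a positive difference, with a median log2 difference of 0.30, but 0 passed limma's test singly, also when adjusted over the list alone, and 6 had an unadjusted p under 0.05. The median was 0.15 without CD4-Vα14Tg replicate 2, 0.15 without WT replicate 1, 0.43 without CD4-Vα14Tg replicate 1 and 0.43 without WT replicate 2. Kif11, Top2a, Cenpe and Uhrf1 had log2 differences of 0.91, 0.72, 0.49 and 0.39, with limma adjusted p from 0.210 to 0.363. Kif11 was at 1.32 without WT replicate 2 (limma adjusted p = 0.0363) and at 0.49 without WT replicate 1, and Top2a ranged from 0.36 to 1.08 over these fits. The camera adjusted p was 4.58e-08, and the adjusted p was 0.555 with an estimated correlation. Type I interferon response genes had a median of 0.08 over 25 genes, with 0 calls by limma and 8 genes at an unadjusted p under 0.05 (camera adjusted p = 0.0271, and adjusted p = 0.701 with an estimated correlation). Oasl2, Oas2 and Usp18 had log2 differences of 0.62, 0.63 and 0.50 and Bst2 had -0.59, and adjusted over the list alone 2 were higher and 1 lower. The interferon list had a camera adjusted p of 0.558 without CD4-Vα14Tg replicate 2 and 0.282 without WT replicate 1.

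Metabolic lists did not pass the set test. Glycolysis had a median of -0.02 over 17 genes against a mean of 0.01 and an upward camera direction (adjusted p = 0.700), and oxidative phosphorylation had -0.07 over 29 genes (adjusted p = 0.670), with 0 calls by limma in both, also when adjusted over the list alone, and 2 and 0 genes at an unadjusted p under 0.05. Of 29 cytosolic ribosomal protein genes, Rps18 fell, with a list median of -0.10 (camera adjusted p = 0.0530, and 0.00879 without CD4-Vα14Tg replicate 1 and 0.00296 without WT replicate 2). Adjusted over the list alone, 1 ribosomal gene was higher and 2 were lower.

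Markers of other cell types showed few calls by limma. At an unadjusted p under 0.05, the lists with 0 calls below had 4 regulatory T cell, 2 γδ T cell, 1 neutrophil, 0 erythroid and platelet, 2 B and plasma cell, 0 hepatocyte and 1 stromal gene. Of the double-positive (DP) thymocyte markers, 5 were tested and Aqp11 fell, with a list median of 0.12 (-0.15 without CD4-Vα14Tg replicate 2), a mean of -0.03, an upward camera direction (adjusted p = 0.722), and 1 higher and 1 lower when adjusted over the list alone. Regulatory T cell markers had 0 calls among 9 (median 0.07, 0.04 to 0.18 when 1 array was left out, camera adjusted p = 0.118). The γδ T cell, neutrophil, and erythroid and platelet lists had 4 tested genes each and 0 calls, and adjusted over the list alone 2 γδ T cell genes were higher and 1 neutrophil gene was lower. B and plasma cell markers had 0 calls among 6 (median -0.03, camera direction up, adjusted p = 0.922), with 1 higher and 1 lower when adjusted over the list alone. Macrophage and monocyte markers had 1 rise among 8, Itgam (median 0.16, 0.05 to 0.13 when 1 array was left out, camera adjusted p = 0.242), which was also the only one adjusted over the list alone. Dendritic cell markers had Ccr9 higher and Irf8 lower among 8 (median -0.21, -0.27 to -0.08 when 1 array was left out, camera adjusted p = 0.242), with 1 higher and 3 lower when adjusted over the list alone. Hepatocyte markers had 0 calls among 7 (median -0.05, mean -0.004, camera direction up, adjusted p = 0.899). Stromal, endothelial and thymic epithelial markers had 0 calls among 11 (median 0.08, camera adjusted p = 0.0847, and 0.0463 without WT replicate 1), with 1 higher when adjusted over the list alone.

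Sex-linked genes differed between arrays in a way the genotype does not describe. Xist, expressed from the inactive X chromosome, was at 10.5 and 5.12 on CD4-Vα14Tg replicates 1 and 2 and at 9.98 and 11.1 on the WT replicates. The Y-linked gene Kdm5d was at 6.40 and 7.45 and at 6.49 and 6.08 on the same arrays, and Eif2s3y was at 7.70 and 8.42 and at 7.72 and 7.04. Uty, also Y-linked, was at 7.09 and 7.84 and at 7.06 and 6.87. CD4-Vα14Tg replicate 1 and the WT arrays thus read Xist and Y-linked genes together, all above array medians of 5.04 to 5.07. A mix of RNA from both sexes in these samples could give this, and the labels do not say whether samples were pooled. When 1 array was left out, CD4-Vα14Tg replicate 2 with its low Xist being 1 of the cases, the median log2 difference of the NKT1 list ranged from -1.49 to -1.24. This range does not tell an effect of sex from an effect of genotype.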

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

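The tests of the other splits of the arrays, of Zbtb16 and of sex, and the comparison of unnamed probe sets with the named ones, were chosen only after the result was seen. The sex test replaced one planned before on the called genes alone, whose choice fixed the direction.

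Probe sets with no gene symbol, or with several, entered no comparison of named genes, and a difference between the genotypes appeared there. Of 9908 such probe sets above the filter, 9 passed limma's test, all 9 higher in CD4-Vα14Tg cells and 0 lower, with log2 rises from 2.37 to 5.89. The largest, probe set 17300129, was at 9.49 and 9.62 on the CD4-Vα14Tg arrays and at 3.17 and 4.15 on the WT arrays, a log2 difference of 5.89 (limma adjusted p = 0.0378). Its WT values lie below the 40th percentile of their arrays, so this difference is set against background. The next, probe set 17300127, was at 10.9 and 11.1 against 4.62 and 5.61, and neither probe set is named here.

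The fall of NKT1 and NKT17 genes, 28 called genes with a median log2 difference of -1.51 (21 NKT1 and 7 NKT17), was weighed against 4 explanations. Admixed conventional T cells without PLZF would lower Zbtb16 by about as much, but its log2 difference was 0.226 (95% interval -0.05 to 0.51), which speaks against them as the whole cause, though the naive T cell markers Igfbp4, Ccr7 and Lef1 rose by 1.97, 1.55 and 0.84, so a smaller share of such cells stays open; DP thymocytes would raise Rag2, Dntt, Ptcra, Cd8a, Cd8b1 and Arpp21, but their median was 0.083 (-0.09 to 0.28), with levels from 3.82 to 6.14 on every array. A difference in sex stays open, since only CD4-Vα14Tg replicate 1 resembles the WT arrays in Xist and Y-linked genes: over all 42 tested genes of both lists its median difference from the WT mean was -1.244 (interval over genes -1.51 to -0.87, 39 genes below both WT arrays), but 1 array carries no spread between samples. The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05: the genotype split called 265 genes, the other splits at most 0, and 1 split reached the count. Each other split puts both genotypes into both groups, so any difference between the genotype groups, whatever its cause, widens its spread. Few calls follow from that alone, so the contrast of counts decides nothing about chance. A different mix of iNKT subsets, stages or organs between the samples and a change of expression within cells both stay open, as these arrays of whole samples do not separate them.

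Small nucleolar RNAs were higher in CD4-Vα14Tg cells in 65 of 71 genes, with a median log2 difference of 0.654, though only 5 were called higher and 1 lower (camera p = 1.13e-26, and p = 0.146 with an estimated correlation). Higher transcription of their host genes could raise those too. The host genes examined were Snhg genes, Gas5 and Taf1d, and their median was -0.054 (bootstrap 95% interval -0.11 to 0.18, 14 genes), without a shared rise. Other hosts of the 71 were not examined, and RNA levels do not measure transcription itself. Higher host transcription therefore stays open beyond these 14 genes. Recovery or labelling of small RNAs may differ between the samples: the median of other small RNA classes was 0.069 over 172 genes (bootstrap 95% interval 0.037 to 0.098), under the bound of 0.10 set in advance to speak against it, but 162 of these are microRNA genes, and these hardly follow small nucleolar RNAs even within a genotype. Between the WT arrays, replicate 1 exceeded replicate 2 by a median of 0.497 for small nucleolar RNAs (62 of 71 genes), 0.377 for 5 small Cajal body RNAs, 0.321 for 3 small nuclear RNAs and 1.69 for 2 Y RNAs (between genotypes 0.21, -0.13 and 1.84), and by only 0.109 for microRNA genes and -0.03 for genes that are not small RNAs, so the bound was a poor one, as judged after the result; between the CD4-Vα14Tg arrays these were 0.282, 0.069, 0.298, 0.524, -0.009 and -0.009, so small Cajal body RNAs did not follow there. The medians of small nucleolar RNAs were 9.65 and 9.27 on the CD4-Vα14Tg arrays and 8.80 and 8.03 on the WT arrays, and their median SD within a group was 0.274 against 0.098 for other genes, so recovery stays open.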

How the results depend on the processing

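The fit without small RNA genes and the counts within lists were chosen after seeing the data, and the other alternatives before. The count of 265 calls stayed within 1.5 times, from 222 to 320, under both other filters, both other scalings, both other variance models, array weights, the mean of probe sets and the fit without small RNA genes, and the share of lower calls moved by under 10 percentage points. The array weights lay from 0.986 to 1.014, so that fit was nearly the main fit and adds no separate support. An adjusted p under 0.10 gives 436 calls by construction. The array numbers are not stated to mark a shared day or animal, and there are only 2 pairs. With the replicate number as a block, the calls were 674 (252 higher, 422 lower), all 265 kept, 11 NKT17 genes and 6 TCR signal genes fell, and the replicate differences of both groups correlated across genes at 0.262. Leaving out 1 array, with the lone array assumed to vary like the other group, gave 166 to 221 calls, 52 to 74 higher and 101 to 147 lower. It gave 3 to 7 NKT17 genes lower, 2 to 3 precursor genes higher and 1 to 2 TCR signal genes lower. Of 38 named genes called, 31 or 32 kept the call without 1 array and none changed sign. Il2rb, Tnfrsf18, Mxd4 and Il6ra lost it without any 1 array, Lef1 without either CD4-Vα14Tg array or WT replicate 1, Sox4 without CD4-Vα14Tg replicate 1 or either WT array, Egr1 without CD4-Vα14Tg replicate 1 or WT replicate 2, and Serpinb1a without replicate 2 of either group. Under the other alternatives 35 to 38 kept it: Il2rb, Tnfrsf18 and Mxd4 lost it with no filter and with quantile normalization, and Tnfrsf18 with median centring. Of 36 named genes that did not pass, 22 passed with the block, among them Il17a, Cd44, Bcl2 and Kif11. With the stricter filter 10 of 35 passed, with the trend 7, with median centring 4, and 0 to 3 under each other alternative. Cd44 and Slamf6 passed in several of these, so a gene given as not passing is not shown to be equal in both groups. Some of these genes differed between replicate numbers in the same direction in both groups. Kif11 read 7.54 and 7.97 on CD4-Vα14Tg replicates 1 and 2, and 6.43 and 7.27 on WT replicates 1 and 2. Il17a read 4.95 and 4.21, and 5.92 and 5.17, on the same arrays. Whether such replicate differences or the smaller number of arrays caused the changes was not tested.

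With an estimated correlation, which uses the correlation among a list's genes, none of the 9 list calls held: adjusted p = 0.298 for NKT1 (median -1.362), NKT17 (-0.764) and TCR signal (-0.294), 0.488 for precursor (0.087), apoptosis (-0.242), immediate early (-0.404) and naive T cell markers (0.449), 0.555 for cell cycle (0.298) and 0.701 for interferon (0.079). Gene correlation alone does not explain this loss. The TCR signal list had an estimated correlation of 0.0043, under the preset 0.01, yet its camera p rose from 2.61e-06 to 0.0373. This form of camera also rests on 2 residual degrees of freedom, so a list that fails it is not shown to be unchanged. fry kept NKT1 and NKT17 (adjusted p = 0.0281 for both) and not TCR signal (0.0878), naive markers (0.10), precursor (0.118), apoptosis (0.177), immediate early (0.208), cell cycle (0.487) or interferon (0.597). It called macrophage markers (0.156, adjusted p = 0.0281) and turned E and Id (-0.011), DP (0.118), B cell (-0.032) and hepatocyte markers (-0.05). Random lists kept all 9, called macrophage (0.0332) and dendritic markers (-0.211, 0.0157), and turned homing (-0.185, 0.0048), B cell (-0.032) and hepatocyte markers (-0.05).

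Other changes concerned lists and genes as follows. SLAM (-0.123) and ribosomal genes (-0.098) passed with no filter, and ribosomal genes also with the stricter filter (-0.126) and the mean of probe sets (-0.109). Camera's direction turned for homing with no filter (-0.185) and with median centring (-0.143), for the TCR complex with the stricter filter (-0.066) and quantile normalization (-0.03), and for hepatocyte markers with quantile normalization (-0.064). Gata3 was 0.004 and Cd5 0.053 with quantile normalization, and 0.011 and 0.040 with median centring. Immediate early genes lost the call without WT replicate 2 (adjusted p = 0.0773), and interferon without CD4-Vα14Tg replicate 2 or WT replicate 1. Without 1 array, medians ranged from -0.072 to 0.013 for the TCR complex, -0.263 to -0.063 for SLAM, -0.248 to -0.058 for homing, -0.009 to 0.180 for interferon, -0.593 to -0.317 for immediate early, -0.076 to 0.056 for E and Id, -0.074 to 0.058 for glycolysis and -0.097 to -0.021 for oxidative phosphorylation. They ranged from -0.172 to -0.043 for ribosomal genes, -0.078 to 0.035 for B cell, -0.165 to 0.089 for hepatocyte and 0.045 to 0.140 for stromal markers. For lists whose call or direction held they ranged from 0.147 to 0.430 for cell cycle, 0.057 to 0.188 for precursor, -0.238 to -0.153 for apoptosis, -0.145 to 0.186 for DP markers, 0.044 to 0.175 for regulatory T cell, 0.052 to 0.130 for macrophage and -0.268 to -0.081 for dendritic markers and -0.006 to 0.072 for NKT2. In the DP and NKT2 lists the median turned and camera's direction did not. Single genes ranged from -0.155 to 0.095 for Gata3, -0.183 to 0.179 for Cd5 and -0.223 to 0.055 for Cd4. Among genes that kept their sign, those moving by over 1.5 times were Il4, Il17a, Egr2, Nr4a1 and Cd69, Kif11 and Top2a, as given with each, and Ptpn22 (-0.788 to -0.376), Cd3e (-0.432 to -0.184), Bcl2 (-1.061 to -0.479), Traf1 (-0.719 to -0.270), Cenpe (0.279 to 0.708) and Usp18 (0.328 to 0.667). The cause was not tested. Signal over background limits Il23r, Il1r1 and Klrc2 in CD4-Vα14Tg cells and Moxd1 in WT cells, whose folds are understated, and Il17a on 1 CD4-Vα14Tg array.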

Other observations

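The gene families here were chosen after their values were seen. Lectin-like NK cell receptors of the Klr families were lower in CD4-Vα14Tg cells: 12 of 15 tested genes, a pseudogene among them, fell, 0 rose, and the median log2 difference was -1.76. Of these 12, Klrb1c, Klrd1, Klrk1, Klrc1 and Klre1 are NKT1 list genes, so the count and median partly repeat that list. Outside the list, Klra5, Klra9, Klrc2, Klri2, Klrb1b, Klrb1f and the pseudogene Klra14-ps fell. Klri2 fell 3.63-fold and Klrb1b fell 3.16-fold, while Klra6 was -1.76 (limma adjusted p = 0.0906) with 6.05 and 7.46 on the WT arrays. Many of these receptors are near-identical copies in the genome, so single members are uncertain. Of 26 interleukin receptor genes, 6 fell and 1, Il6ra, rose, and Il2rb and Il6ra lost the call when any 1 array was left out. The 6 that fell, Il12rb2, Il18rap, Il2rb, Il1r1, Il23r and Il17re, are all NKT1 or NKT17 list genes. Il6ra is an NKT2 list gene, so these calls repeat the list results. Il12rb2 and Il18rap, parts of the receptors for interleukin-12 and interleukin-18, fell 3.58-fold and 2.52-fold. Of 19 chemokine genes, 3 fell and 0 rose: Ccl5 (4.43-fold), Xcl1 (2.96-fold) and Ccl3 (2.22-fold). Ccl5 and Xcl1 are NKT1 list genes and Ccl3 is not. Integrin genes went both ways, with 3 of 19 higher (Itga4, Itgb3 and Itgam) and 2 lower (Itga1 and Itgae). Itgb3 rose 2.13-fold.

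TCR α variable segments gave mixed values, and their copies cannot be separated on this array. Of 18 probe sets named with 1 of 5 Trav segments, 6 had a higher and 12 a lower mean in CD4-Vα14Tg cells. Trav12-2 is among the 83 genes called higher by its brightest probe set (log2 difference 0.95, limma adjusted p = 0.0313). Only 1 of its 6 probe sets was higher, with a median of -0.825, so that call does not hold for the segment. Its probe sets 17299849 and 17299926 read the same on every array, as did 17299857 and 17299934. The counts of 6 and of 18 probe sets thus repeat some measurements. Of the 3 probe sets of Trav7-4, 1 read 7.13 and 7.26 on the CD4-Vα14Tg arrays against 2.90 and 3.71 on the WT arrays, where it lay below the 40th percentile, so no exact difference follows. Another read 3.66 and 4.08 against 4.78 and 4.88, below that percentile on the CD4-Vα14Tg arrays. The 5 probe sets of Trav9d-3 ranged from -1.01 to 0.30.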
